A study of Homo sapiens with 16 samples.

How the data were processed

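Reverse-transcription (RT) stops were measured in HEK293T, HCT116 and HCT116-shDKC1 cells, 16 libraries in 8 groups of 2 replicates. Per the labels, polyadenylated RNA was fragmented and treated with or without CMC, and some CMC-treated samples also with Terminator exonuclease. Per the labels, reads were trimmed with cutadapt 2.8 and aligned with STAR, version not given, to the human genome build hg38. Per the name column of the tables, positions came from rtsSeeker, whose further filters are not stated. The 10 tables each set a treated library beside a CMC- control library, position by position. HEK293T CMC- libraries appear in both the CMC+ and the Terminator tables, with 99.93 and 99.92 percent of shared positions equal within 0.0001.

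Per the file headers, stop reads and covering reads are counts in the HCT116 and HCT116-shDKC1 Terminator tables, where every value is whole. In the HEK293T tables and the HCT116 tables without Terminator the deposited stop and covering reads are expected counts, with fractions. How reads that match several positions were counted is not stated. The authors also give stop reads as RPM (scaled to a common library depth), and count divided by RPM gave a constant library total in every column used except the controls of the HCT116 tables without Terminator, whose RPM was not used. Those totals, listed per library at the start of the results, served as library sizes in the fits without those controls. From the values, where control coverage was used, a position was listed only with at least 5 treated stop reads, at least 1 control stop read and a treated stop ratio not below that of the control. A position absent from a table is therefore not a position without stops. The tables give 31 bases of sequence around each position, the gene and the strand.

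Gene names were taken from the tables. Of the positions with an Ensembl transcript, 84.1 percent had a transcript version in GENCODE 29 (hg38), and the base matched at 100 percent of those. Regions (5′ UTR, CDS, 3′ UTR, noncoding exon) come from that annotation and are left out elsewhere. 18S bases are numbered as the position in the annotated 18S transcript less 1, which places the hypermodified uridine at 1248. Other rRNA positions are given in the genome. Positions that share a 31-base sequence are called copies.

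Counts were fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with expected counts rounded to whole numbers for edgeR and DESeq2. Tested positions were listed in every table of the fit and had at least 10 stop reads in at least 2 libraries. HEK293T libraries formed a fit of 21266 positions before that filter. The Terminator tables of HCT116 and HCT116-shDKC1 formed another of 30328, and the HCT116 tables without Terminator another of 39679. The replicate number was a block in the fits of stop reads, because the series design text describes each replicate as a CMC- and CMC+ pair. As a check, log2 stop RPM was set against the mean of its group. These deviations were correlated across positions between libraries with the same number. The correlation was 0.24 to 0.45 between groups of the same cell population, and 0.15 to 0.36 between groups of HCT116 and HCT116-shDKC1. No label pairs wild type with knockdown, so the check does not establish the pairing. P-values were adjusted by Benjamini-Hochberg over all tested positions of a comparison, U and other bases together. A position was called at an adjusted p under 0.05 with a fold of at least 2. The SE of a log2 change is its size divided by the square root of the F statistic. P-values of edgeR, DESeq2 and fry measure only the spread between these samples. Fisher's exact tests treat genes or positions as independent units and carry no spread between libraries. The same holds for Wilson and bootstrap intervals, which treat positions as units. Intervals of read ratios cover counting error only, since reads without molecular identifiers are not independent molecules.

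The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Comparisons were CMC+ against CMC-, CMC+ with Terminator against CMC-, and CMC+ with Terminator against CMC+ in HEK293T; the first 2 in HCT116; the second in HCT116-shDKC1; and the interaction between Terminator response and knockdown. Interaction classes of positions with a mean log2 response of at least 1 against coverage were tested with fry in edgeR, 14 classes as a family. Transcript levels of knockdown against wild type used covering reads of the CMC- libraries, summed per gene over the positions listed in all Terminator tables of HCT116 and HCT116-shDKC1, with TMM scaling, at least 10 reads per gene, and an adjusted p under 0.05 with no fold minimum. That fit had no replicate block, because the labels do not pair a wild-type library with a knockdown library. Transcript levels are a proxy here, because tables list selected positions. Lists, motifs and shared positions were tested with two-sided Fisher's exact tests in scipy 1.17.1, against genes or U that were tested.

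The 19 fixed lists were cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, H/ACA ribonucleoproteins, stand-alone pseudouridine synthases, box C/D and nucleolar proteins, snoRNA host genes, nuclear long noncoding RNAs, mitochondrially encoded genes, mitochondrial ribosome and oxidative phosphorylation, chaperones, glycolysis, cytoskeleton, splicing factors and hnRNPs, proteasome and ubiquitin, histones and chromatin, cell cycle and p53 targets, colorectal epithelial markers, and HEK293T markers. The motifs were those of TRUB1 and PUS7 and a run of 3 U. At the transcript level 18 of the lists had a tested gene; the stand-alone synthases had 0.

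Named positions followed a rule. For each comparison it takes the called U with the same sign in both replicates, 1 per gene with the smallest p, and of these the 12 largest rises and 12 largest falls. It adds the 6 called structural RNA positions with the highest mean count, DKC1, and up to 4 members per list with the highest mean count. The results name those that matter most. Interaction positions, shared mRNA positions and the positions compared between 3 HEK293T groups were chosen after their values were seen. Where the control group held 3 stop reads or fewer, the ratio of stop RPM is given with an exact (Clopper-Pearson) 95% interval. Shares of U carry 95% Wilson intervals.

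Alternatives were TMM scaling, DESeq2 1.42.0 with its own size factors, no filter, a minimum of 30 stop reads, no replicate block, an offset of log covering reads (called against coverage in the results), leaving out structural and mitochondrial RNA, and leaving out each library. For lists and motifs a fold of at least 4 was tried. Identical sequences counted once, fits on the tables of a comparison alone, and some settings for lists, motifs and shared positions were chosen after seeing the data. Because of the listing rule, the stop ratio of a treated library is not below that of the control in the same table, so falls against coverage are hardly ever seen within such a pair. HEK293T CMC- values were taken from the Terminator tables. They differed from those of the CMC+ tables at 24 of 14824 tested positions, where the tables gave different sequences, and 1 of these (RACK1, log2 -2.19, not U) was called lower against coverage with CMC alone. Fits on positions with the same sequence in every table, also chosen after seeing the data, left 14470 of these.

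The design was departed from in these ways. HCT116 libraries were planned as a single fit, but the tables without Terminator hold fractional counts, and their control columns equal those of the Terminator tables at only 22.08 and 21.72 percent of shared positions, so they were not tied to a sample and were fitted apart. Of those control columns only the stop reads were used, as libraries of the CMC- group with no number and no pair. The fit of HCT116 CMC+ against CMC- therefore had no replicate block and no coverage offset, and its library sizes were the sums of stop reads at the 39679 positions listed in both tables. A rise was named there where both CMC+ libraries lay above the mean of the controls. Not used here were 164 further columns of per-library values. HCT116 CMC+ with and without Terminator were therefore set side by side with no test. The ribosomal protein list was restricted to protein-coding genes. Bootstrap intervals of medians used 10000 draws.

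The steps were tested on simulated data. With 200 changed positions at a 4-fold change, edgeR recovered 99.5 percent (HEK293T CMC+ versus CMC-, 13773 positions), 100 percent (both HEK293T Terminator comparisons, 13790 positions), 99.5 percent (HCT116 and HCT116-shDKC1 with Terminator, 25273 and 25322 positions) and 99.5 percent (HCT116 CMC+, 19268 positions), and DESeq2 74.5, 75.5, 74.5, 58.5, 71 and 96 percent in that order of comparisons. At a 2-fold change edgeR recovered 29.8 to 38 percent in these comparisons, and DESeq2 0 to 12 percent. For the interaction edgeR recovered 78.5 percent at 4-fold (25328 positions) and 15 percent at 2-fold (25286 positions), and DESeq2 35.5 and 5 percent. All these position changes were simulated as rises, for the interaction in the knockdown Terminator libraries, without the listing rule. Losses at single positions in the knockdown were not simulated. For transcript levels it recovered 34 percent at 1.5-fold and 88 percent at 2-fold (2372 genes). fry called 10 percent of 20 simulated classes of 200 U with no shift and 100 percent at a shift of -0.25. The simulated positions varied independently, with known dispersions and the same shift at each. Recovery in real classes can therefore be lower.

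A second simulation kept every stop ratio unchanged but let coverage differ and applied the listing rule. Under library totals edgeR then called 1447 of 5706 positions for HEK293T Terminator versus CMC-, 700 for Terminator versus CMC+ and 0 for CMC+ versus CMC-. It called 511 and 551 of 5723 for HCT116 and HCT116-shDKC1 with Terminator and 0 for the interaction. HCT116 CMC+ was not simulated in this way. With the coverage offset it called 1 for HEK293T Terminator versus CMC- and 0 in the other comparisons. Calls under library totals with Terminator thus include coverage changes. With the offset the median log2 change was 0.42 for HEK293T Terminator versus CMC- and 0.44 for HEK293T CMC+ versus CMC-. It was 0.26 in HCT116 and in HCT116-shDKC1 with Terminator, so the listing rule alone raised changes against coverage. Random gene lists passed the Fisher test at 2.8 percent. Other tools were limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.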

Results

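Reverse-transcription stops were measured in polyadenylated RNA of HEK293T cells (a human embryonic kidney line), HCT116 cells (a human colorectal carcinoma line) and HCT116-shDKC1 cells, which carry a short hairpin against DKC1. DKC1 encodes dyskerin, the pseudouridine synthase of the H/ACA small nucleolar ribonucleoproteins, which guide RNAs direct to uridines (U) of ribosomal and spliceosomal RNA. CMC is a carbodiimide that binds pseudouridine and leaves an adduct at which reverse transcriptase stops, so a stop that is more frequent with CMC than without marks a candidate pseudouridine. Some libraries were also treated with Terminator, an exonuclease that digests RNA with a 5′ monophosphate. The 16 libraries fell into 8 groups of 2 replicates: HEK293T without CMC (CMC-), with CMC (CMC+) and with CMC and Terminator, HCT116 with the same 3 treatments, and HCT116-shDKC1 without CMC and with CMC and Terminator.

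The library totals behind the authors' RPM (reads scaled to a common library depth) are given in reads, replicate 1 first. HEK293T libraries held 19100000 and 15700000 (CMC-), 14900000 and 17500000 (CMC+), and 16300000 and 15800000 (CMC+ with Terminator). HCT116 libraries held 27300000 and 31300000 (CMC-), 8650000 and 9980000 (CMC+), and 22500000 and 24000000 (CMC+ with Terminator). HCT116-shDKC1 libraries held 29600000 and 29500000 (CMC-), and 23200000 and 26900000 (CMC+ with Terminator). The tables listed 719918 distinct positions, with a median of 49.1 to 213 covering reads per library column. Below, a stop percent is stop reads over covering reads (mean ± SD, n = 2), a log2 change is that of stop RPM (± SE), and a called position passed an adjusted p of 0.05 with a fold of at least 2. Coordinates are on hg38.

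The first question was which uridines CMC alone marks in HEK293T. Counting repeated copies, most of the uridines that rose lay in ribosomal RNA (rRNA). At 18S rRNA base 966 (RNA18SN2, chromosome 21 position 8210596) the stop percent rose from 2.35 ± 0.21 without CMC to 7.68 ± 0.84 with it (log2 1.53 ± 0.13, adjusted p 0.0059), and at 18S base 1692 from 2.62 ± 0.0885 to 7.07 ± 0.0127 (log2 1.18 ± 0.13, adjusted p 0.00788). In 28S rRNA (RNA28SN1) position 8443007 of chromosome 21 rose from 2.91 ± 0.234 to 10.0 ± 0.245 percent (log2 1.47 ± 0.14, adjusted p 0.00742). Ribosomal RNA is the classical target of H/ACA-guided pseudouridylation. Of 5837 tested U, 66 were called higher and 0 lower by edgeR (376 higher and 5 lower at an unadjusted p under 0.05), and DESeq2 called 34 higher and 0 lower. Of 8987 tested positions of other bases 3 were called higher. These 66 stood for 27 distinct 31-base sequences, because rRNA genes are repeated, and 60 of them lay in rRNA. The median change of all 14824 tested positions was 0.14, and scaling with TMM, which removes that shift, called 3 U, copies of 18S base 966 (TMM log2 1.41, adjusted p 0.0285). The 66 calls fell to 1 without the replicate block, to 0 without CMC+ replicate 2 and to 1 without CMC- replicate 2.

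Small RNAs and mitochondrial RNA supplied the other HEK293T sites of CMC alone. RNU4-1, a U4 spliceosomal RNA gene (ENSG00000200795.1), rose at nucleotide 72 (chromosome 12 position 120293166) from 5.06 ± 3.16 to 33.1 ± 5.62 percent (log2 2.36 ± 0.37, adjusted p 0.0311). The mitochondrial tRNA gene MT-TF rose at position 605 (log2 1.83 ± 0.21, adjusted p 0.0122), MT-TM at 4425 (log2 1.53 ± 0.16, adjusted p 0.00869), and the large mitochondrial rRNA MT-RNR2 at 3067, from 2.28 ± 0.155 to 5.08 ± 0.793 percent (log2 1.04 ± 0.13, adjusted p 0.00909). RNA5-8SN1, a 5.8S rRNA gene, rose at chromosome 21 position 8439890 from 3.83 ± 0.059 to 8.9 ± 0.0821 percent (log2 1.03 ± 0.14). The only called mRNA uridine was in the 5′ UTR of the histone gene HIST1H4C (log2 1.79 ± 0.23, adjusted p 0.0488), and against its coverage the rise was 0.88 with an adjusted p of 0.86. The DKC1 mRNA itself, at X position 154762912, was at 18.5 ± 0.402 percent with CMC and 4.29 ± 2.02 without, a difference that did not pass (adjusted p 0.808). It rested on 12 stop reads against 3, a ratio of 4.28 with a counting interval of 1.16 to 23.7. RNU4-1, MT-TF and MT-TM had TMM adjusted p-values of 0.14, 0.0638 and 0.0569.

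With Terminator, stops at these uridines were more frequent still. The stop percent at the distinct U called with CMC alone was higher with Terminator than without at 26 of 27 positions, with a median of 2.35 without CMC, 7.07 with CMC and 12.3 with CMC and Terminator. 18S base 34 went from 7.09 ± 0.194 to 14.2 ± 0.347 percent, 18S base 822 from 13.7 ± 0.845 to 21.2 ± 0.263, and RNU4-1 nucleotide 72 from 33.1 ± 5.62 to 48.9 ± 0.104. The exception was HIST1H4C, at 64.9 ± 11.4 percent with CMC and 53.2 ± 1.28 with CMC and Terminator.

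**Figure D1:**
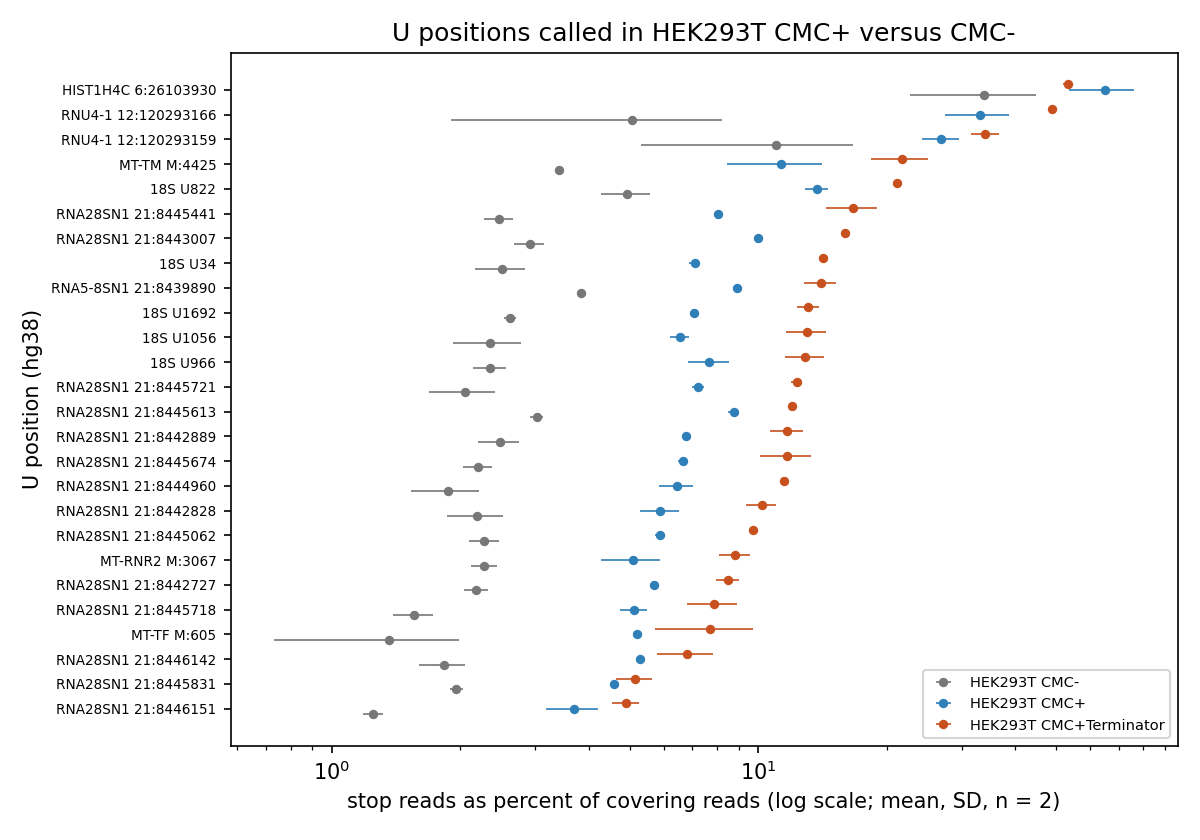
Stop reads as percent of covering reads (log scale, mean with SD, n = 2) at 26 of the 27 distinct U positions called in HEK293T CMC+ versus CMC-, in the 3 HEK293T groups. At most positions the values rise from CMC- through CMC+ to CMC+ with Terminator, with HIST1H4C as an exception.

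The comparison of Terminator-treated CMC+ libraries with CMC- libraries asked which uridines the full procedure marks in HEK293T, mRNA included. In rRNA, 28S position 8443007 reached 16.0 ± 0.199 percent against 2.91 ± 0.234 (log2 2.97 ± 0.11, adjusted p 8.38e-07), and 18S base 1692 reached 13.1 ± 0.768 against 2.62 ± 0.0885 (log2 2.83 ± 0.10). 18S base 1248, where textbooks place the hypermodified pseudouridine of the small subunit, went from 17.2 ± 2.75 to 35.4 ± 0.741 percent (log2 1.46 ± 0.10). Among mRNAs, the coding sequence of CALR, which encodes the chaperone calreticulin (ENSG00000179218.13, chromosome 19 position 12940843), rose from 3.81 ± 0.462 to 25.3 ± 0.363 percent (log2 2.95 ± 0.25, adjusted p 1.98e-05). PSAP, which encodes prosaposin, rose at chromosome 10 position 71816664 from 5.43 ± 0.672 to 26.6 ± 2.85 percent (log2 2.92 ± 0.19). TRIM28, which encodes a transcriptional corepressor, rose at chromosome 19 position 58549791 from 2.17 ± 0.144 to 11.1 ± 0.737 percent (log2 2.85 ± 0.22).

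Of the 5837 U, 1794 were called higher (1353 distinct sequences) and 2 lower, and 3163 positions of other bases were called higher. The median change of all tested positions was 0.82. With TMM, which sets changes relative to that shift, 246 U were called higher and 95 lower, and 45 positions of other bases were called higher. Against coverage 1038 U and 787 positions of other bases were called higher, so U made up 56.9 percent of the calls in place of 36.2. Leaving out a library gave 971 to 1796 U. Relative to the median shift, with TMM, CALR rose by 2.16 (TMM adjusted p 0.00371), PSAP by 2.13, TRIM28 by 2.07 and 28S position 8443007 by 2.17. Some of the largest changes rested on 3 control reads in all. DKC1 (log2 3.07 ± 0.31) had 25 stop reads against 3, a ratio of 9.01 (interval 2.75 to 46.6), and so had the RNA-binding protein gene HDLBP (log2 3.06 ± 0.32). The tryptophan tRNA gene tRNA-Trp-CCA-2-1 had 24 against 3, a ratio of 8.65 (2.63 to 44.9), and ETF1, a termination factor gene, had 21 against 3, a ratio of 7.57 (2.26 to 39.6). Set against coverage, HDLBP stayed past the threshold (log2 2.48, adjusted p 0.00534), while DKC1 (log2 1.65, adjusted p 0.0956) and ETF1 (log2 1.5, adjusted p 0.146) did not. SRRM2 (2.74), WDR34 (2.72) and RNPS1 (2.62) completed the named log2 rises.

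By RNA class, the called shares with Terminator in HEK293T lay close together for U and other bases of mRNA, rRNA and mitochondrial RNA under library totals, and against coverage rRNA U were called more often than other rRNA bases. In mRNA 34.05 percent of 2887 tested U were called, against 38.13 percent of 3659 other bases. In rRNA 44.5 percent of 1526 U were called, against 43.31 percent of 3787 other bases. Mitochondrial RNA had 3.72 and 3.63 percent, and pseudogenes 6.39 and 8.36. Against coverage, 22.87 percent of rRNA U and 3.46 percent of other rRNA bases were called, and in mRNA 18.01 and 14.32 percent. Long noncoding RNA had 15.52 percent of U and 19.92 percent of other bases called against coverage, and mitochondrial RNA 8.93 and 7.37. Spliceosomal RNA U were called at 55.56 percent against coverage, other bases there at 7.69 percent. Nuclear tRNA genes had 6 of 7 U called against coverage, and 0 of 10 other bases by edgeR.

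The first 20 nucleotides of mRNAs had the highest share of called U in HEK293T and HCT116 under library totals, and other bases there were called as well. In HEK293T with Terminator 75.7 percent of the U at nucleotides 1 to 20 were called (81 of 107), against 30.6 percent beyond nucleotide 100, and for other bases 83.1 (108 of 130) and 34.6 percent. Set against coverage the order was opposite, with 1.9 and 19.2 percent, and with TMM 0.9 and 0.6 percent were called. In HCT116 the same windows had 85.0 and 15.4 percent of U under library totals (92.3 and 26.3 percent of other bases), 70.0 and 6.5 percent with TMM, and 10.0 and 37.9 percent against coverage. The knockdown had 85.0 percent of U called at nucleotides 1 to 20 and 87.2 percent at 21 to 50 under library totals. U in 5′ UTRs were called more often than other mRNA U in HEK293T (odds ratio 2.69, two-sided Fisher's exact test, p 1.61e-08), but less often against coverage (odds ratio 0.369, p 0.000479). Capped mRNA ends resist Terminator.

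**Figure D2:**
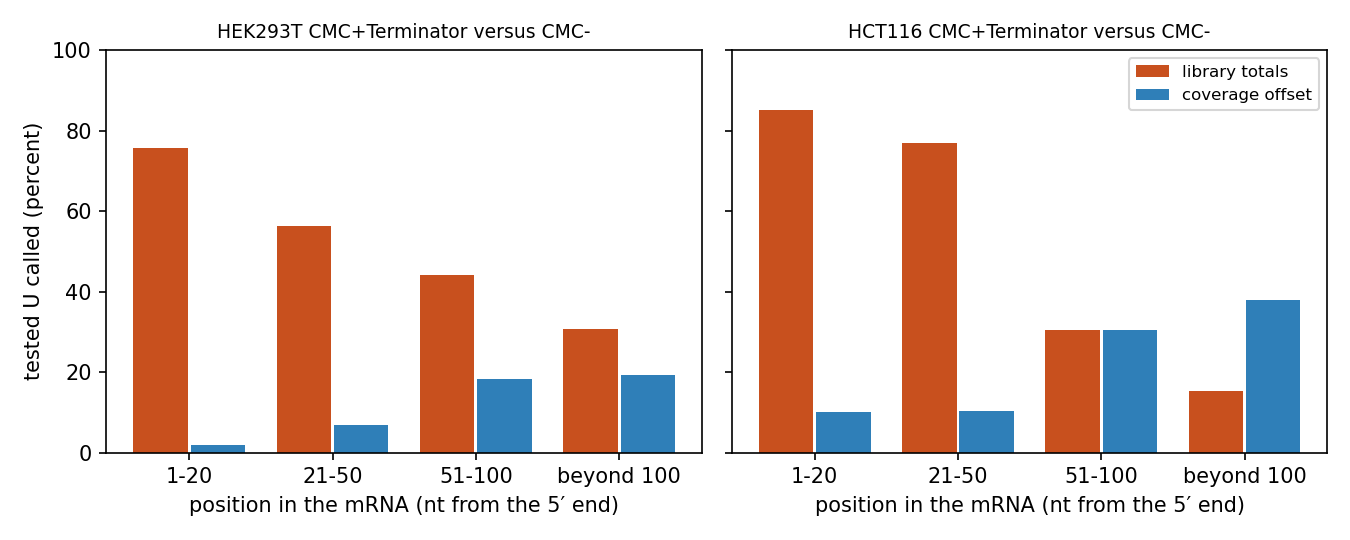
Percent of tested mRNA U called higher in CMC+ with Terminator than in CMC-, by distance from the 5′ end in nucleotides, for HEK293T (left) and HCT116 (right). Bars for library totals fall with distance, from 75.7 to 30.6 percent in HEK293T, while bars for stops set against coverage rise, from 1.9 to 19.2 percent.

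The comparison of HEK293T CMC+ libraries with and without Terminator asked what the exonuclease adds. The 45S precursor gene RNA45SN1 rose at chromosome 21 position 8441139 from 3.82 ± 0.277 to 7.82 ± 0.806 percent (log2 2.03 ± 0.12, adjusted p 9.64e-06, against coverage 1.05, adjusted p 0.0146). STOML2, which encodes a mitochondrial membrane protein, rose from 15.2 ± 0.497 to 32.8 ± 0.256 percent (log2 1.92 ± 0.19, adjusted p 4.73e-05). The ribosomal protein gene RPL36 rose from 5.49 ± 0.786 to 11.1 ± 0.533 percent (log2 1.65 ± 0.16, against coverage 1.07, adjusted p 0.0218). Most other named mRNA rises lay near 5′ ends and did not pass against coverage: RPL13 (log2 1.86, against coverage 0.25), ATP5ME (1.84 and 0.30) and RPL34 (1.74 and 0.36). The signs of VIM (1.87), RNF187 (1.85) and CCNB1 (1.71) were negative against coverage, at -0.04, -0.16 and -0.27. PSAP rose by 1.70 (against coverage 0.90, adjusted p 0.216).

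The count of U called higher with Terminator than without was 1058, with 9 lower, and 2434 positions of other bases were higher. The median change was 0.68, and relative to it, with TMM, 42 U were higher and 290 lower, and 79 positions of other bases higher and 251 lower. Against coverage 73 U were higher and 0 lower (edgeR, with 911 higher and 2 lower at an unadjusted p under 0.05, and 25 lower by DESeq2 under its own size factors). Of other bases, 60 were higher and 1 lower against coverage. The largest falls were at HSP90AB1, an HSP90 chaperone gene (log2 -1.39 ± 0.20, adjusted p 0.00948, TMM -2.06), SRRM2 (-1.31 ± 0.22, TMM -1.98), the thioredoxin gene TXN (-1.26 ± 0.21, TMM -1.92), and mitochondrial MT-CO1 (-1.23 ± 0.21, TMM -1.90). PABPC1 fell by 1.10 on the log2 scale, while against coverage its change was 0.38. The DKC1 site did not pass (log2 1.06 ± 0.23, adjusted p 0.0718), and its sign was opposite against coverage (-0.40).

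In HCT116, CMC without Terminator was compared with the control columns of the same tables, which hold stop reads only here, so log2 changes are relative to the stop reads listed. The mRNA of the ribosomal protein gene RPL19 (ENSG00000108298.11, chromosome 17 position 39201278, exon 1) had 19.1 and 16.3 stop reads with CMC against 2.0 and 3.1 without (log2 2.62 ± 0.34, adjusted p 0.0467, TMM 0.0526). The large mitochondrial rRNA MT-RNR2 rose at 3067, the position called in HEK293T as well (log2 1.54 ± 0.16, adjusted p 0.026). The U4 RNA genes RNU4-2 (log2 1.49 ± 0.16, adjusted p 0.0269) and RNU4-1 (log2 1.47 ± 0.16, adjusted p 0.028) rose at nucleotide 79. In rRNA, 18S base 1056 rose by 1.13 ± 0.09 (adjusted p 0.022), and in 28S rRNA position 8445674 by 1.3 ± 0.13 (adjusted p 0.026), 8444993 by 1.22 ± 0.09 (adjusted p 0.022), 8445721 by 1.12 ± 0.08, 8446151 by 1.06 ± 0.08 (all of RNA28SN1) and 8216508 of RNA28SN2 by 1.07 ± 0.14 (adjusted p 0.0484).

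Of 5893 tested U, 21 (10 distinct sequences) were called higher and 0 lower in that HCT116 comparison (edgeR, with 257 higher and 187 lower at an unadjusted p under 0.05, and 22 higher and 0 lower by DESeq2). Of 14767 tested positions of other bases 4 were called higher and 18 lower, and these 18 lay in rRNA. With copies counted, ribosomal RNA held 17 of the 21 U, snRNA 2, mitochondrial RNA 1 and mRNA 1. The median change was -0.06, and TMM, relative to it, called 31 U higher and 0 lower. Without CMC+ replicate 1 there were 0 calls, and without CMC+ replicate 2 also 0. DKC1 had no tested U there.

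The added Terminator step in HCT116 was set beside CMC alone without a test, because the tables with Terminator hold whole counts and those without hold fractional counts. At the 10 distinct U called with CMC alone, the median stop percent was 5.66 with CMC and 7.79 with CMC and Terminator, and 10 of 10 were higher with Terminator. RPL19 was at 11.8 ± 3.61 and 19.9 ± 2.58 percent, 18S base 1056 at 6.21 ± 0.0736 and 8.68 ± 0.135, 28S position 8444993 at 4.87 ± 0.0811 and 7.27 ± 0.216, MT-RNR2 position 3067 at 3.1 ± 0.155 and 4.31 ± 0.159, RNU4-1 nucleotide 79 at 34.6 ± 2.37 and 38.9 ± 0.0793, and RNU4-2 nucleotide 79 at 31.6 ± 3.9 and 34.7 ± 5.54.

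The full procedure in HCT116, CMC and Terminator against CMC-, marked uridines in spliceosomal RNA, mitochondrial tRNA, rRNA and mRNA. The U1 RNA gene RNU1-1 rose at nucleotide 5 (chromosome 1 position 16514281) from 2.26 ± 0.11 to 12.7 ± 1.16 percent (log2 4.20 ± 0.20, adjusted p 7.37e-08), and U1 pairs with 5′ splice sites through its 5′ end. RNU5A-1 rose at nucleotide 43 from 3.88 ± 0.177 to 43.9 ± 8.64 percent (log2 3.31 ± 0.33, adjusted p 5.29e-06). The mitochondrial valine tRNA gene MT-TV rose at 1666 from 2.38 ± 0.219 to 19.4 ± 0.784 percent (log2 3.46 ± 0.24). In 28S rRNA position 8444960 rose from 1.82 ± 0.204 to 13.9 ± 1.11 percent (log2 2.95 ± 0.13) and position 8444993 from 1.32 ± 0.00638 to 7.27 ± 0.216 (log2 2.8 ± 0.13). The alanine tRNA gene tRNA-Ala-CGC-4-1 rose by 3.76 ± 0.37 and RPS13 by 3.63 ± 0.37, the latter by 1.61 against coverage (adjusted p 0.0252).

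Other large HCT116 rises rested on 2 or 3 control reads. RPL15 had 39 stop reads against 2, a ratio of 24.5 (counting interval 6.36 to 210), MT-TF 35 against 2, a ratio of 22.0 (5.66 to 189), and the lamin gene LMNB2 26 against 2, a ratio of 16.4 (4.1 to 142). BSG, which encodes basigin, had 32 against 3 (13.4, interval 4.2 to 68.5), and the glutamate tRNA gene tRNA-Glu-TTC-2-1 had 22 against 2 (13.8, interval 3.4 to 121). All 5 passed with TMM and against coverage.

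The count in HCT116 with Terminator was 1928 of 9660 U higher (968 distinct sequences) and 8 lower, with 4870 of 16493 positions of other bases higher and 13 lower. The median change was 0.44, and relative to it, with TMM, 989 U were higher and 584 lower, and 2318 positions of other bases higher and 656 lower. By class, 38.61 percent of rRNA U and 41.7 percent of other rRNA bases were called higher, 18.35 and 30.57 percent in mRNA, 49.78 and 25.35 percent in snRNA, and 44.61 and 25.0 percent in tRNA. Against coverage the rRNA shares were 27.89 percent for U and 19.45 for other bases, and those in mRNA 36.6 and 40.97 percent. The 6 named falls had the opposite sign against coverage: the mitochondrial-derived MTRNR2L12 (-1.46 ± 0.28, adjusted p 0.000804, against coverage 0.30), KRT8P46 (-1.21, 0.18), MT-ND4L (-1.19, 0.22), EEF1A1 (-1.19, 0.04), EEF1A1P9 (-1.10, 0.41) and FTH1P15 (-1.10, 0.05). A position is listed only where its stop ratio was not lower with CMC, so a fall in stop reads at a listed position goes with a fall in coverage.

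The knockdown was first examined at DKC1 itself. In the CMC- columns of the Terminator tables, DKC1 mRNA was covered at 0.44 and 0.48 RPM per listed position in HCT116 (2 and 3 positions) and at 0.186 and 0.068 in HCT116-shDKC1 (2 and 1 positions). These means cover unlike positions: 154768327 (20 reads) was listed only in HCT116 replicate 2, and 154762868 (2 reads) only in HCT116-shDKC1 replicate 2. At X position 154762871 the covering reads were 8 and 11 in HCT116 and 5 in HCT116-shDKC1 replicate 1, and at 154762874 they were 14 in HCT116 replicate 2 and 6 in HCT116-shDKC1 replicate 1. In HEK293T, stop reads at X position 154762912 were 2 and 1 without CMC, 6 and 6 with CMC, and 12 and 13 with CMC and Terminator. No DKC1 position was listed in all 4 Terminator tables of HCT116 and HCT116-shDKC1, so its difference between wild type and knockdown was not tested.

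In the knockdown, the named rises with CMC and Terminator against CMC- lay in spliceosomal RNA, mitochondrial and nuclear tRNA, rRNA, mRNA and a pseudogene. RNU1-1 nucleotide 5 rose from 1.71 ± 0.787 to 11.5 ± 0.0979 percent (log2 4.60 ± 0.22, adjusted p 1.07e-07), and MT-TV position 1666 from 2.11 ± 0.829 to 20.4 ± 1.23 percent (log2 3.65 ± 0.23). 28S position 8444960 rose from 2.02 ± 0.201 to 13.6 ± 0.998 percent (log2 2.94 ± 0.13), and 8444993 from 1.44 ± 0.114 to 5.32 ± 0.224 percent (log2 2.34 ± 0.13). The mRNA rises at RPS24 (log2 3.59), ARF1 (3.57), CNIH1 (3.39) and RPS27A (3.28) did not pass against coverage (1.21, 1.26, 1.02 and 0.64). tRNA-Ala-CGC-4-1 had 40 stop reads against 3 (ratio 15.7, interval 5.0 to 79.3), and the pseudogene STAG3L1 had 25 against 2 (14.7, interval 3.67 to 128).

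In HCT116-shDKC1 1731 of 9660 U were called higher and 28 lower (12 distinct sequences), with 4636 positions of other bases higher and 19 lower. The median change was 0.39, and relative to it, with TMM, 867 U were higher and 580 lower, and 2342 positions of other bases higher and 682 lower. The named falls again had the opposite sign against coverage: PPIA (-1.14, against coverage 0.38), MTND2P28 (-1.04, 0.18), RPL41 (-1.04, 0.18), EEF1A1P6 (-1.02, 0.11), EEF1A1P13 (-1.02, 0.14), RPL17 (-1.02, 0.17), EEF1A1 (-1.01, 0.04) and MT-ND2 (-1.0, 0.08).

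Whether the response to CMC with Terminator against CMC- depends on DKC1 was tested as an interaction, the knockdown response minus the wild-type response. No library had Terminator without CMC, so the effects of the treatments cannot be separated. Tested positions were listed in both replicates of wild type and knockdown, so their stop ratio in the knockdown was not below its control. Uridines whose response was lost in the knockdown could drop out before the test. The absence of calls cannot exclude such losses. Under library totals no position passed with all libraries: 0 U were called higher or lower by edgeR, with 21 higher and 166 lower at an unadjusted p under 0.05. DESeq2 called 0, with 0 higher and 24 lower at an unadjusted p under 0.05, and TMM called 0, with 42 and 159. Of other bases 0 were called, but 17 were called lower without knockdown Terminator replicate 2 and 17 without knockdown CMC- replicate 2, while U stayed at 0. In simulated data with 200 changed positions edgeR recovered 78.5 percent of 4-fold and 15 percent of 2-fold interactions, and DESeq2 35.5 and 5 percent. These were simulated as rises in the knockdown Terminator libraries without the listing rule, so the recovery of losses is unknown. Among the smallest p-values, chosen after the values were seen, was 18S base 1445. It went from 3.3 ± 0.227 percent without CMC to 10.4 ± 0.181 with CMC and Terminator in wild type. In the knockdown it went from 3.32 ± 0.378 to 5.81 ± 0.598 percent. Its interaction was -0.69 ± 0.17 (adjusted p 1) under library totals and -0.86 ± 0.11 (adjusted p 0.0167) against coverage. Against coverage 3 copies of a 28S position, 8218168 of RNA28SN2, were called lower (-1.08 ± 0.15, adjusted p 0.0167).

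By class, the rRNA uridines that responded to CMC with Terminator, 45S precursor positions included, leaned lower in the knockdown. So did the other bases of rRNA. Classes took listed positions with a mean response of at least 1 over wild type and knockdown. Strong losses in the knockdown could therefore be left out. The median interaction was -0.11 at 219 rRNA U, of which 70.3 percent were lower, and -0.08 at 510 rRNA positions of other bases, of which 59.4 percent were lower. Against coverage these medians were -0.22 (84.5 percent lower) and -0.17 (70.4 percent lower). At a mean response of at least 1.5, 84 percent of 106 rRNA U and 64.1 percent of 170 other positions were lower, and against coverage 91.5 and 71.2 percent. The median log2 response at rRNA U was 1.66 and 1.69 in the wild-type replicates and 1.43 and 1.34 in the knockdown replicates. snRNA U (42 positions) had a median of -0.21, snoRNA U (9 positions) -0.49, tRNA U (36) -0.01, mitochondrial U (142) -0.14 and mRNA U (780) -0.12. H/ACA particles serve rRNA and spliceosomal RNA, while mitochondrial and most tRNA sites have stand-alone synthases. fry, which tests whether a class moves on balance in a single direction and does not compare it with other classes, gave rRNA U p 0.358 (adjusted 0.494 over 14 classes), snRNA U p 0.0447 (adjusted 0.125) and snoRNA U p 0.038 (adjusted 0.125). Other classes gave like values: U in the TRUB1 motif (6 positions, median -0.53) p 0.0364, snRNA positions of other bases (9, median -0.13) p 0.0321 and mRNA positions of other bases (1267, median -0.12) p 0.0341, each adjusted to 0.125. Against coverage rRNA U gave p 0.0299 (adjusted 0.146). None of the 14 classes passed the adjusted threshold under library totals, TMM, the coverage offset or without the replicate block.

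**Figure D3:**
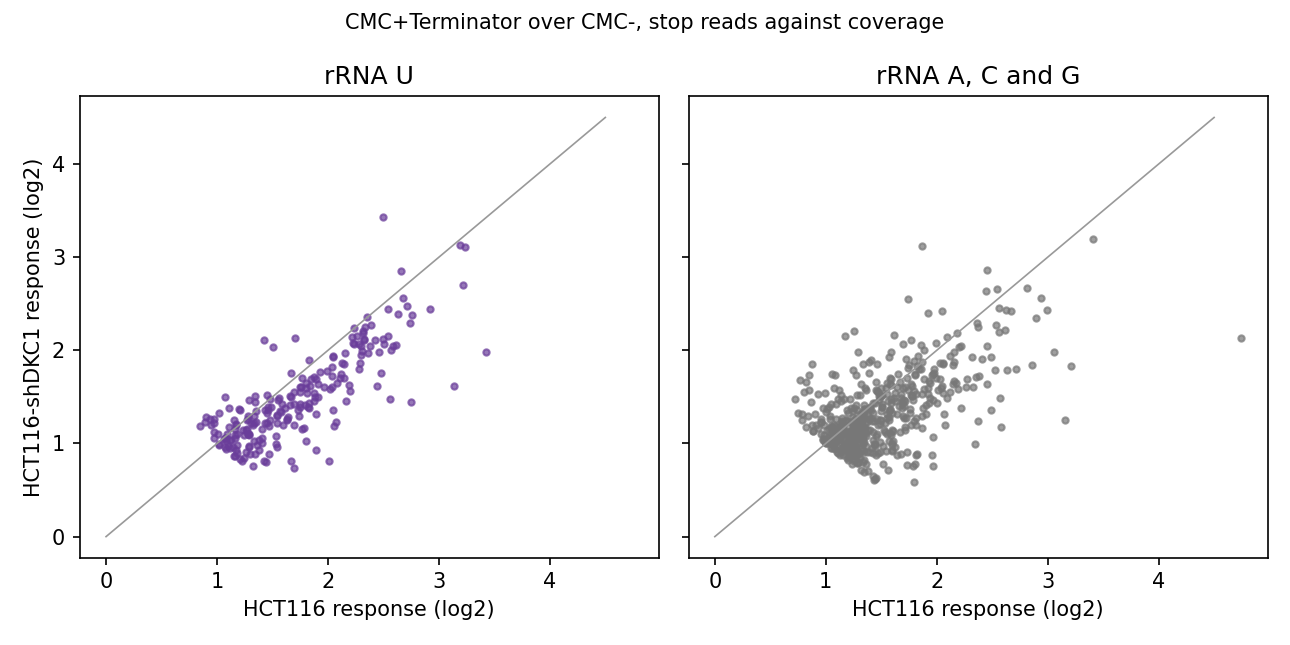
Log2 response to CMC with Terminator over CMC- (stop reads against coverage) in HCT116 (horizontal) and HCT116-shDKC1 (vertical) at rRNA U (left) and other rRNA bases (right), each point a position and the line equality. Of the 219 U points 84.5 percent lie below the line, and the other bases lean below it too, by a median of -0.17.

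At the transcript level, estimated from the coverage of listed positions in the CMC- libraries of wild type and knockdown, 3 of 2372 genes were higher in the knockdown and 11 lower (edgeR with TMM, with 40 higher and 110 lower at an unadjusted p under 0.05). The ribosomal protein gene RPL24 rose from 2.2 ± 0.0192 to 5.84 ± 0.552 covering RPM per listed position (log2 1.38 ± 0.17, adjusted p 3.16e-05) and the WNT antagonist gene DKK1 by 1.34 ± 0.28 (adjusted p 0.0215). MT-ND6 rose from 2.25 ± 0.0387 to 4.01 ± 1.71 (log2 0.82 ± 0.19, adjusted p 0.0434), with a wide spread between the knockdown replicates. The chondroitin-synthesis gene CHPF fell from 2.61 ± 0.457 to 1.13 ± 0.00955 (log2 -1.23 ± 0.17, adjusted p 8.51e-05) and the glucose transporter gene SLC2A1 by 1.30 on the log2 scale (adjusted p 0.0393). The lipid-synthesis genes SCD (-0.81 ± 0.12, adjusted p 0.000362) and FASN (-0.58 ± 0.12) fell, as did PDIA3 (-0.84), CLDN4 (-0.77), NTSR1 (-0.77), HSPB1 (-0.70), FAT1 (-0.65), IER3 (-0.58) and the keratin gene KRT19 (-0.54). RPL24, DKK1 and SLC2A1 were covered at 2, 1 and 1 listed positions. This fit had no replicate block. With the block 125 genes were called (39 higher and 86 lower), with library totals 3, and leaving out a library gave 3 to 26.

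Genes of the fixed lists were also counted at the transcript level, and no test of a list as a whole was made there. The 80 ribosomal protein genes had a median of 0.10 with 1 higher, both over all genes and adjusted over the list alone. The 3 colorectal epithelial markers had a median of -0.54 with 2 lower, also adjusted over the list alone. Chaperones (20 genes) had 1 lower and, adjusted over the list alone, 3, and the mitochondrially encoded genes (33) had 1 higher under both. The cytoskeleton list (19) had 0 and, adjusted over the list alone, 1 lower, and the cell cycle and p53 list (11) had 0 and, adjusted over the list alone, 1 higher and 1 lower. The other lists had 0 calls by edgeR under both adjustments, with medians that included 0.33 for 6 aminoacyl-tRNA synthetases and -0.28 for 8 proteasome and ubiquitin genes. H/ACA proteins were represented by NHP2 alone (log2 0.19, not past the threshold).

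The cell lines were compared at U tested with Terminator in both. Among 2151 such U, 773 were called in HEK293T and 639 in HCT116, and 482 in both, where 230 would be shared by chance (odds ratio 12.9, two-sided Fisher's exact test, p 1.71e-135). These U include copies. With identical sequences counted once, 214 of 1362 were shared where 87.1 would be by chance (odds ratio 12.2, same test, p 1.99e-69). The overlap of other bases was not tested. Among 467 mRNA U, 57 were shared where 28.5 would be by chance (odds ratio 5.68, p 2.98e-12). Called in both lines under library totals and against coverage were 23 mRNA U. They included RPL19 at 39201278 (log2 2.17 ± 0.28 in HEK293T and 2.81 ± 0.44 in HCT116), TRIM28 at chromosome 19 position 58547450 (2.10 ± 0.20 and 1.64 ± 0.30), RPL37A at 216499392 (1.81 ± 0.14 and 2.34 ± 0.24), RPL11 (1.43 and 1.30) and CAPNS1 (1.62 and 2.29), and sites in EEF2, RACK1, PTBP1, ALDOA, CD81, UBE2S, RPL23 and CANX. These were chosen after the values were seen, and positions next to each other are not independent.

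The share of U among listed positions measured how specific a rise in stop ratio was. With at least 20 treated stop reads, 29.8 percent of the positions listed for HEK293T with Terminator were U. That share rose to 62.5 percent at a stop-ratio fold of at least 2 in both replicates, 91.2 percent at 3 and 95.3 percent at 4. Most of the 239 positions at a fold of 3 were repeated: 207 had a sequence listed more than once, and 93.7 percent of these were U. Sequences listed once had 45.2 percent U at a fold of 2 and 75.0 percent (24 of 32) at 3. HEK293T with CMC alone went from 34.0 to 93.4 percent at a fold of 2 and 100 percent of 21 positions at 3. HCT116 with Terminator went from 28.6 to 40.5, 53 and 62.3 percent, and the knockdown from 28.9 to 39.3, 53.4 and 62.4 percent. Repeated sequences carried most of that rise, reaching 66.3 percent U at a fold of 4 in HCT116 and 66.7 percent in the knockdown. For sequences listed once the shares were 33.2, 39.2, 40.8 and 35.7 percent in HCT116. In the knockdown they were 33.6, 36.4, 41.7 and 41.7 percent. In mRNA, 43.7 percent of 261 HEK293T positions with Terminator were U at a fold of at least 2. There, 70.0 percent of 20 HEK293T positions with a fold of at least 3 were U (95% Wilson interval 48.1 to 85.5), against 28.1 percent of 96 HCT116 positions (20.1 to 37.8).

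**Figure D4:**
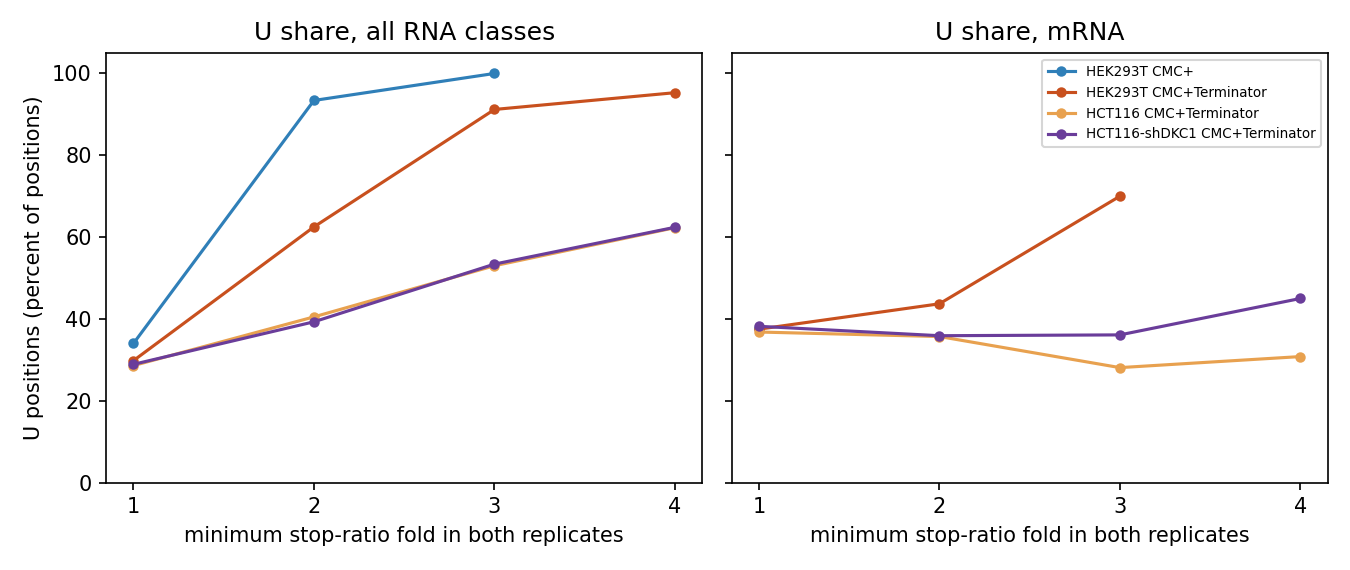
Percent of listed positions that are U (vertical) by minimum stop-ratio fold in both replicates (horizontal), at positions with at least 20 treated stop reads, for all RNA classes (left) and mRNA (right), each line a group and points with few positions left out. At a fold of at least 3 in mRNA HEK293T with Terminator lies at 70.0 percent and HCT116 with Terminator at 28.1 percent.

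Sequence around called U was tested against the motifs of 2 stand-alone synthases, TRUB1 and PUS7, and a run of 3 U, by two-sided Fisher's exact tests adjusted over 3 motifs per comparison. In HCT116 with Terminator 11 of the 12 tested U in the TRUB1 motif were called (odds ratio 44.4, p 1.92e-07, adjusted 5.76e-07), and in the knockdown 9 (odds ratio 13.8, p 2.44e-05, adjusted 7.32e-05). TRUB1 modifies the T loop of tRNAs. The PUS7 motif was enriched in HCT116 with Terminator (odds ratio 1.79, p 0.000646, adjusted 0.000969) and with CMC alone (3 of 21 called U, 7.03, p 0.0125, adjusted 0.0375), but not past the threshold in the knockdown (1.45, p 0.0392, adjusted 0.0588). Against coverage it passed in both, with odds ratios of 1.65 in HCT116 (p 0.00164, adjusted 0.00246) and 2.48 in the knockdown (p 1.48e-08, adjusted 4.44e-08). With identical sequences counted once, which was chosen after seeing the data, it passed neither in HCT116 with Terminator (1.13, p 0.664, adjusted 0.664) nor with CMC alone (1 of 9 called U, 5.41, p 0.188, adjusted 0.564). The run of U passed in no comparison under library totals with every listed position and a fold of at least 2 (in HCT116 with CMC alone 1.48, p 0.647, adjusted 0.971). At a fold of at least 4 it passed in HCT116 with Terminator (1.42, adjusted p 0.0453), and with identical sequences counted once it was depleted in HEK293T with Terminator against CMC- (0.63, adjusted p 0.0107). Against coverage it passed in HEK293T with Terminator against CMC- (1.49, p 0.0049, adjusted 0.00735), in HCT116 with Terminator (1.26, p 0.0229, adjusted 0.0229) and in the knockdown (1.37, p 0.00314, adjusted 0.00314). In HEK293T with Terminator 4 of 6 TRUB1 sites were called (odds ratio 4.52, p 0.0764, adjusted 0.115) and PUS7 had an odds ratio of 1.07 (p 0.815). Against coverage these were 9.28 (p 0.011, adjusted 0.011) and 2.23 (p 0.000987, adjusted 0.00296). In HEK293T with CMC alone PUS7 did not pass under library totals (2.09, p 0.258, adjusted 0.774) and passed against coverage (4.79, p 3.15e-05, adjusted 9.45e-05). Whether the motif results differ between cell lines or with the knockdown was not tested.

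Genes of the fixed lists were tested for carrying a called U, by two-sided Fisher's exact tests adjusted over the lists of a comparison that had a tested gene (16 lists in HCT116 with Terminator and in the knockdown, 17 in HEK293T). In HCT116 with Terminator 49 of 76 ribosomal protein genes carried a called U, against 504 of 1158 other genes (odds ratio 2.35, p 0.000488, adjusted 0.0078), with 100 U called over all and 71 adjusted over the list alone. All 8 snoRNA host genes did (p 0.00158, adjusted 0.00843; 21 U and 14 adjusted over the list alone), all 8 glycolysis genes (p 0.00158, adjusted 0.00843; 20 and 20), 12 of 14 cytoskeleton genes (odds ratio 7.53, adjusted p 0.00875; 34 and 27) and 21 of 29 mitochondrially encoded genes (3.32, adjusted p 0.0122; 39 and 31). These genes also had more tested U each. Counted per U, the called share was 11.9 percent in ribosomal protein genes against 20.7 percent elsewhere (odds ratio 0.517), and 2.9 against 22.7 percent for mitochondrially encoded genes (0.103).

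The remaining lists in HCT116 with Terminator did not pass. Genes with a called U, U called over all, and U called when adjusted over the list alone were as follows. Translation factors had 11 of 15 genes (28 and 15), chaperones 10 of 13 (13 and 11), nuclear long noncoding RNAs 2 of 6 (7 and 5), the mitochondrial ribosome and oxidative phosphorylation list 6 of 8 (6 and 7), splicing factors and hnRNPs 4 of 8 (4 and 4), proteasome and ubiquitin 4 of 5 (5 and 4), and histones and chromatin 3 of 3 (11 and 11). H/ACA ribonucleoproteins, box C/D and nucleolar proteins, cell cycle and p53 targets, and colorectal markers had 1 of 1 each. Aminoacyl-tRNA synthetases, stand-alone pseudouridine synthases and HEK293T markers had 0 tested genes there.

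In the knockdown, ribosomal protein genes (47 of 76, odds ratio 2.93, p 7.59e-06, adjusted 0.000121; 87 U and 72 adjusted over the list alone), translation factors (11 of 15, 4.73, adjusted p 0.0223), snoRNA host genes (7 of 8, 12.0, adjusted p 0.0223) and glycolysis genes (7 of 8, 12.0, adjusted p 0.0223) passed. In HEK293T no list passed for Terminator against CMC- (ribosomal proteins 58 of 75, adjusted p 0.574; 154 U and 143 adjusted over the list alone) or for CMC alone. In HCT116 with CMC alone no list passed either. For Terminator against CMC+ in HEK293T the glycolysis genes passed (9 of 10, odds ratio 15.8, p 0.000809, adjusted 0.0138; 23 U and 19 adjusted over the list alone). None of the 10 list results that passed in these comparisons remained with a fold of at least 4. Counted per U, a setting chosen after seeing the data, the called share of all 10 lay below that of other genes, and for 6 of them this passed. In the knockdown these shares were 10.4 against 18.6 percent for ribosomal protein genes, 6.1 against 18.4 for translation factors, 8.4 against 18.1 for snoRNA host genes and 14.5 against 18 for glycolysis genes. For glycolysis genes with Terminator against CMC+ in HEK293T they were 12.8 against 18.3 percent.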

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

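The coverage-offset interaction test behind the positions below was planned; the tests that weigh explanations (the comparisons with other bases and with mitochondrial U) were chosen after the result was seen. The CMC response here is that to CMC with Terminator against CMC-. At 4 rRNA uridines it differed between wild-type HCT116 and the DKC1 knockdown by the interaction test when stops were set against coverage. Each was lower in the knockdown. These passed an adjusted p of 0.05, and only position 8218168 also reached the 2-fold change that a call needs. 18S base 1445 (RNA18SN2, chromosome 21 position 8211075) went from 3.3 ± 0.227 to 10.4 ± 0.181 percent in wild type and from 3.32 ± 0.378 to 5.81 ± 0.598 percent in the knockdown (n = 2), an interaction of -0.86 ± 0.11 (adjusted p 0.0167, edgeR). In RNA28SN2, position 8218168 had -1.08 ± 0.15 (adjusted p 0.0167), position 8218233 had -0.84 ± 0.12 (adjusted p 0.0206) and position 8217756 had -0.77 ± 0.11 (adjusted p 0.0267). Under library totals the same interactions were -0.69 ± 0.17, -0.72 ± 0.21, -0.66 ± 0.18 and -0.72 ± 0.18, each with an adjusted p of 1.

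The weighed pattern is the lower CMC response at rRNA U in the knockdown, a median of -0.22 against coverage over 219 U. A weaker response of the knockdown libraries at all bases is a technical explanation, and it needs other rRNA bases to be lower by a like amount: their median was -0.17 over 510 positions, and rRNA U lay only -0.05 from it (95% bootstrap interval -0.11 to -0.0), so this explanation may account for part of the pattern. The shares below 0 were 84.5 percent for U and 70.4 percent for other bases, a difference that was not tested. Loss of DKC1-dependent pseudouridine is the biological explanation that the design gives. It predicts a lower response at rRNA U than at mitochondrial pseudouridines, which other synthases make. The difference between rRNA U and mitochondrial U was -0.05 (interval -0.13 to 0.04). The 2 cannot be told apart over these 219 and 142 positions because the interval includes 0. Both sets of U were picked by their response, not as known pseudouridines, so this comparison cannot decide on the explanation. The 219 U included positions annotated to the 45S precursor, which were not tested apart from mature rRNA. A difference confined to mature rRNA could therefore be missed. So could U whose response was lost in the knockdown, which the listing rule can leave out. The 4 positions lie further below the other bases than the class does, but they were picked for that and exclude nothing. Both explanations stay open, and knockdown and library preparation are confounded in these groups.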

How the results depend on the processing

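Identical sequences counted once, the same sequence in every table, fits on a comparison's own tables, lists counted per U, motifs and lists against coverage, and the mRNA, TMM, coverage and identical-sequence settings of the shared positions were chosen after seeing the data; the other settings were planned. Counts are U called higher unless said. The cause of a change was not tested unless given.

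TMM, which removes the median shift, called 3 (HEK293T CMC+ versus CMC-, from 66), 246 (Terminator versus CMC-, from 1794), 42 (Terminator versus CMC+, from 1058; U lower 290, from 9), 31 (HCT116 CMC+, from 21, stays within 1.5 times), 989 (HCT116 Terminator, from 1928) and 867 (knockdown, from 1731). DESeq2 called 34, 202, 41 (25 lower), 22, 476 and 453 in that order. The coverage offset called 198, 1038 and 73 (0 lower) in the first 3, and 3 U lower in the interaction, from 0; in HCT116 and the knockdown with Terminator it stayed within 1.5 times, at 2613 and 2116. A minimum of 30 stop reads, which leaves fewer positions, called 614 for HEK293T Terminator versus CMC-, 602 for Terminator versus CMC+ (0 lower), 1031 in HCT116 and 1000 in the knockdown with Terminator. Leaving out structural and mitochondrial RNA, which held many of the called U, left 0, 1014, 247 (3 lower), 0, 508 and 394. Without the replicate block, which ignores the pairing, HEK293T CMC+ versus CMC- had 1 call, and the other counts stayed within 1.5 times. HCT116 CMC+ had no block to leave out, and no filter gave 16. Identical sequences counted once gave 24, 582 (Terminator versus CMC+), 6, 940 and 840. The distinct sequences called before were 27, 640, 10, 968 and 864, so counting copies once accounts for part of the fall, and the rest was not tested. The tables of HEK293T Terminator versus CMC- alone, which share more positions, gave 3582. Positions with the same sequence in every table gave 66, 1733, 1026 (8 lower), 21, 1916, 1721 and, in the interaction, 0.

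Leaving out a library assumed that the lone sample varies like the other groups. HEK293T CMC+ versus CMC- gave 0 to 63 calls: 0 without CMC+ replicate 2, 1 without CMC- replicate 2 and 36 without CMC+ replicate 1, so that count rests on single libraries. Terminator versus CMC- gave 971 to 1796 (1075 without Terminator replicate 1, 971 without Terminator replicate 2, 1067 without CMC- replicate 1). Terminator versus CMC+ gave 538 to 1059 (538 without CMC+ replicate 2, 657 without Terminator replicate 2), and its U lower 2 to 8 (2 without Terminator replicate 1, 2 without Terminator replicate 2, 3 without CMC+ replicate 1, 2 without CMC+ replicate 2). HCT116 CMC+ gave 0 to 24 (0 without CMC+ replicate 1, 0 without CMC+ replicate 2), so it needs both CMC+ libraries. HCT116 Terminator gave 1543 to 1935, the knockdown 1257 to 1732 and the interaction 0 to 0. In the interaction 17 positions of other bases were called lower without knockdown Terminator replicate 2 and 17 without knockdown CMC- replicate 2, from 0.

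At the transcript level 14 genes became 3 with library totals, 125 with a replicate block (39 higher and 86 lower), 8 with DESeq2 and 13 with no filter. Leaving out a library gave 3 to 26 (26 without HCT116 CMC- replicate 1, 5 without HCT116 CMC- replicate 2, 3 without knockdown CMC- replicate 1, 7 without knockdown CMC- replicate 2).

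The 10 list results became 0 with a fold of at least 4 and 0 when U were counted in place of genes, where 6 lists passed with a share below other genes; against coverage there were 12. The 4 motif results, all enrichments, became 7 enrichments with a fold of at least 4, 10 against coverage and 2 with identical sequences once, where the run of 3 U in HEK293T Terminator versus CMC- passed on the other side (odds ratio 0.63, adjusted p 0.0107). The PUS7 motif in HCT116 CMC+ reversed, to an odds ratio of 0.0, with a fold of at least 4, where 1 U was called. The odds ratio of shared positions stayed past the threshold in every setting, from 4.75 to 29.4.

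Of the named positions, TMM left 71 on the same side of the threshold and 14 no longer past it, and the coverage offset left 36 and 23. Against coverage 19 reversed, which the listing rule favours for falls against CMC-. For HEK293T Terminator versus CMC+ these were VIM (-0.04), RNF187 (-0.16), CCNB1 (-0.27), PABPC1 (0.38) and DKC1 (-0.40). For HCT116 Terminator they were MTRNR2L12 (0.30), KRT8P46 (0.18), MT-ND4L (0.22), EEF1A1 (0.04), EEF1A1P9 (0.41) and FTH1P15 (0.05). In the knockdown they were PPIA (0.38), MTND2P28 (0.18), RPL41 (0.18), EEF1A1P6 (0.11), EEF1A1P13 (0.14), RPL17 (0.17), EEF1A1 (0.04) and MT-ND2 (0.08).

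The alternatives for HCT116 CMC+ with against without Terminator were not run, since that comparison had no fit, and the coverage offset of HCT116 CMC+ versus CMC- was not run, since control coverage was not used there. At 2-fold edgeR recovered 29.8 to 38 percent of simulated rises, and 15 percent for the interaction. Changes of that size or smaller at single positions can thus be missed. Losses at single positions in the knockdown were not simulated.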

Other observations

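All tests in this part were chosen after the result was seen. In HEK293T, 3163 positions of bases other than U rose with Terminator against CMC-, with a median log2 change of 1.24. Higher read coverage at the same positions is a candidate explanation: with stops set against coverage 589 of them, 18.6 percent, were still called, and their median fell from 1.24 (median SE 0.17) to 0.64 (median SE 0.15), below the log2 change of 1 that a call needs. With unchanged stop ratios in simulated data, the listing rule alone gave a median of 0.42 against coverage. The 0.64 may therefore overstate the rise in stop ratio. Whether scaling by library totals is a cause cannot be told: with TMM 45 of them, 1.42 percent, were still called, but TMM lowered the change of all tested positions by nearly the same amount (mean 0.80, SD 0.00388), so calls are lost whatever the cause. Stops spreading from a neighbouring U that rose do not account for most of them, since 310, 9.8 percent, lay next to a called U. No biological explanation was tested, and coverage and scaling stay open.

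Among mRNA positions with a stop-ratio fold of at least 3 in both replicates, the share of U was 28.1 percent in HCT116 and 70.0 percent in HEK293T with Terminator. Copies among these mRNA positions do not explain it, since they were few: counting identical sequences once gave 29 percent of 93 positions in HCT116 (95% Wilson interval 20.8 to 38.9). That count cannot speak to copies in pseudogenes, which were left out beforehand. At mRNA positions with a sequence listed once the share was 32.7 percent of 55 in HCT116 and 73.7 percent of 19 in HEK293T. Few control stop reads do not explain it either, since at positions with at least 5 control stop reads the share was 28.3 percent of 92 (20.1 to 38.2) in HCT116 and 66.7 percent of 18 (43.7 to 83.7) in HEK293T. The HCT116 tables hold whole counts and the HEK293T tables fractional counts, which was not tested as a cause. A difference between the cell lines stays open as well and was not tested apart from the tables.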
